A study of Homo sapiens with 4 samples.

How the data were processed

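RNA of HepG2 cells was measured by RNA sequencing in 4 libraries. Per the labels' protocols, libraries were made from total RNA with an Illumina TruSeq kit. FastQC, Trimmomatic, TopHat2 2.0.10 and Cufflinks were used, per the submitters' processing notes, which give no order or settings. The genome build and gene annotation are not given in the sources used here, so no coordinates are printed. The deposited table gives 1 value per gene symbol and library for 23368 symbols. It is named as FPKM, but its values were not length-scaled. In each library 100% of the values were whole multiples of a single step, within a tolerance of 1e-06, whatever the gene. The deposited signal was therefore reads per gene divided by a size factor per library. The factors were 0.856 in shCtrl, 1.11 in shPJA1, 1.76 in TGFb1 and 0.614 in the library titled shPJA/TGFb1, and median-ratio size factors recomputed from the recovered reads came out equal. Values are called normalized counts here. The comparisons had been planned for FPKM, and the same size rule was applied to normalized counts.

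Groups followed the treatment labels, fixed before the data were examined. One library is titled shPJA/TGFb1 while its treatment label says water and the series' design text lists an untreated control in its place. It was grouped as water, and every comparison with it gives both names. Comparisons that follow its title, with shPJA1 as its partner without TGFb1 and TGFb1 as its partner without the hairpin, were added after seeing the data. The labels do not say whether the TGFb1 library carried a control hairpin. Each condition has 1 library, so pairs of libraries were compared without a test. The depth ranged from 990698 to 2848665 reads, and 3 reads, the floor used for a count of 0, correspond to a normalized count of 1.71 in TGFb1 and 4.89 in the library titled shPJA/TGFb1.

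Genes with a mean normalized count of at least 1 over the 4 libraries were kept (13387). Ratios were taken as log2 of the normalized count plus 1, which understates the change of low genes, and genes at or beyond 2-fold were counted. Ratios quoted with an interval are plain ratios of normalized counts, with an exact conditional 95% interval of 2 Poisson counts. The number expected from counting error alone came from 100 Poisson simulations of each pair with no difference. Of 33 gene lists fixed before the data were examined, 31 had at least 5 kept members, 1 of the others, the endothelial markers, had 4, and the mitochondrially encoded genes had 0 in the table. A list's median was placed among 10000 random lists matched in 20 bins of expression, and lists below percentile 2.5 or above 97.5 are said to stand apart. This describes the libraries and is no test across replicates.

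Genes are named by a rule fixed in advance. It takes PJA1 and the TGF-beta label-check genes, the 15 highest and 15 lowest genes of each comparison without small RNAs and uncharacterised loci, up to 4 members of each list with the largest change, and up to 10 genes beyond 2-fold in both planned comparisons. Genes quoted at a mean of at least 20, those quoted as alike in both pairs, and LSAMP, IER3, RASD1, ZC3H4, BIRC3 and TMED9 in the count fit were chosen after their values were seen. Some results that the rule selects are withheld and not reported here.

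As an added alternative, edgeR 4.0.16 was run in R 4.3.3 on the recovered reads of 10210 genes with at least 40 reads, with TMM scaling, quasi-likelihood tests, Benjamini-Hochberg adjustment and additive terms for the hairpin and TGFb1 by title. With 1 residual degree of freedom the spread was shared across genes, at a common coefficient of variation of 10.9%. DESeq2 1.42.0 was run on the same model. Transcript GC content and length came from the GENCODE release 29 transcripts, matched by symbol for 98.9% of the genes of a mean of at least 20. A lowess trend of each library's deviation on GC content (span 0.3) was subtracted, or used as an offset in edgeR. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

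The steps were tested on simulated data. For the TGFb1 term the changed genes were drawn from those with at least 100 reads. With 10074 genes in the fit, edgeR called 83 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and 10 of 10010 unchanged genes. These reads were simulated with the fitted common spread and exact additivity, and with no hairpin effect or GC trend. The simulation therefore does not give the rate of false calls in the real libraries. For shPJA1 against shCtrl, with 13387 genes, the changed genes were drawn from those of a mean of at least 20. Beyond 2-fold were 200 of 200 genes changed 4-fold and 22 of 8365 unchanged genes of that mean. Of 200 random lists, whose genes varied independently, 6 stood apart. So did 50 of 50 lists raised by 0.3, drawn from genes of a mean of at least 20. Recovery of genes below these levels was not simulated. The alternatives were other pseudocounts, filters on low values, scalings and fold rules, unmatched random lists, crossed controls, and count fits with another scaling or filter or with a term dropped or replaced.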

Results

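Total RNA of HepG2, a human liver cancer cell line that keeps many hepatocyte genes active, was sequenced in 4 libraries, with 1 library per condition. A lentiviral short hairpin RNA against PJA1, a RING-type E3 ubiquitin ligase, gave the shPJA1 library, and a control hairpin gave the shCtrl library. A further library was labelled as treated with TGF-beta1, a cytokine whose receptors signal through SMAD2 and SMAD3, and the protocol gives 200 pM for 1 hour. The last library carried conflicting labels. Its title names both the PJA1 hairpin and TGFb1, while its treatment label says water. It is called here the library titled shPJA/TGFb1, and it entered the planned comparisons as the water control. The reads assigned to genes numbered 1363318 in shCtrl, 1784689 in shPJA1, 2848665 in TGFb1 and 990698 in the library titled shPJA/TGFb1. With 1 library per condition no difference below has a replicate check. The intervals are 95% exact intervals of a ratio of 2 read counts, and the floors are 3 reads. Both cover counting error only.

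PJA1, the targeted gene, was low in 2 of the 4 libraries. Its normalized count was 50.3 in shCtrl, from 43 reads, and 38.2 in TGFb1, from 67 reads. It was 15.3 in shPJA1, from 17 reads, and 9.78 in the library titled shPJA/TGFb1, from 6 reads. PJA1 in shPJA1 was 0.30 times its level in shCtrl (0.16 to 0.55), which is 69.5% lower. In the library titled shPJA/TGFb1 it was 0.19 times the shCtrl level (0.068 to 0.46) and 0.26 times the TGFb1 level (0.091 to 0.59). In TGFb1 it was 0.76 times the shCtrl level, with an interval that holds 1 (0.51 to 1.14). The level of PJA1 therefore went against the water label of that library, and directions drawn from that label below carry this limit.

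The genes fixed in advance for checking the TGFb1 label were mostly higher in the library titled shPJA/TGFb1 too. SMAD7, an inhibitory SMAD that TGF-beta switches on within the first hour, had a normalized count of 83.0 in shCtrl and 69.3 in shPJA1, against 168.0 in TGFb1 and 158.1 in the library titled shPJA/TGFb1. Against shCtrl the ratio of SMAD7 was 2.02 (1.56 to 2.66) in TGFb1 and 1.91 (1.39 to 2.63) in the library titled shPJA/TGFb1. Between TGFb1 and the library titled shPJA/TGFb1 it was 1.06 (0.84 to 1.35). KLF10, a TGF-beta-inducible transcription factor, was 1.47 times higher in TGFb1 than in shCtrl (1.29 to 1.67) and 1.38 times higher in the library titled shPJA/TGFb1 than in shPJA1 (1.18 to 1.6). SKIL, which encodes a SMAD corepressor, had ratios of 1.59 (1.31 to 1.94) and 1.14 (0.92 to 1.41) in these comparisons, and ID1 had 1.67 (1.16 to 2.46) and 1.39 (0.95 to 2.02). JUNB and ID3 were higher in the library titled shPJA/TGFb1 than in shPJA1, at 2.04 (1.40 to 2.97) and 1.96 (1.08 to 3.57), but not in TGFb1 against shCtrl, at 0.95 (0.67 to 1.35) and 0.70 (0.42 to 1.20). PMEPA1 had at most 12 reads in any library.

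**Figure D1:**
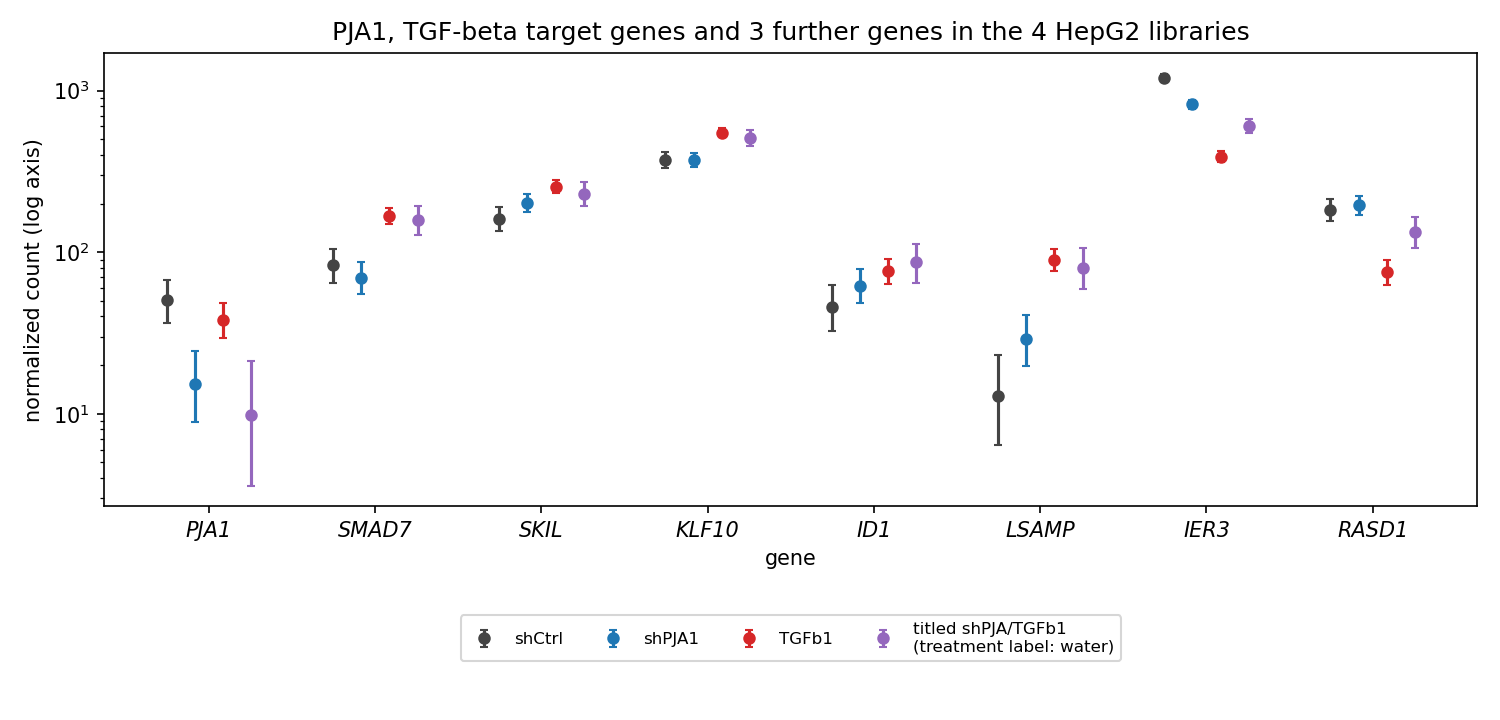
Normalized count (log axis) of 8 genes in each of the 4 libraries, with bars for the 95% exact Poisson interval of the reads. PJA1 was lowest in shPJA1 (15.3) and the library titled shPJA/TGFb1 (9.78), and SMAD7 and LSAMP were highest in TGFb1 (168.0 and 89.4) and the library titled shPJA/TGFb1 (158.1 and 79.9).

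The comparison of shPJA1 with shCtrl asked which genes differ when PJA1 is knocked down. Among 13387 genes with a mean normalized count of at least 1, 538 were at least 2-fold higher and 564 at least 2-fold lower in shPJA1, on the log2 scale with a pseudocount of 1. The same 2 libraries simulated with counting error and no difference gave 986 genes on average, so most of the 1102 lie within the range of low-count noise. CREB3L3, a liver transcription factor anchored in the endoplasmic reticulum, led the genes higher in shPJA1, with 17 reads against 0, which is at least 4.37-fold against the floor. It also had 20 reads in TGFb1 and 4 in the library titled shPJA/TGFb1, so shCtrl alone had 0. TAS2R31, VAX2, PRDM1, NKD2 and TBCA followed, with 7 to 9 reads against 0. At the other end CSF3, which encodes the cytokine G-CSF, had 0 reads in shPJA1 and 8 in shCtrl, at least 3.46-fold lower. The glycolytic enzyme gene PFKM had 0 against 5, and IL1B had 0 against 4.

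Genes read more deeply gave smaller but better measured differences between shPJA1 and shCtrl. In a filter chosen after seeing the data, a mean normalized count of at least 20, 8575 genes remained. Of these 24 were higher and 20 lower by 2-fold, against 25.2 expected in total from counting error. All 44 had an interval that excludes 1. The genes named next were picked from the ends of this ranking, so their intervals do not tell them apart from counting error. MYOF, which encodes myoferlin of the plasma membrane, was 2.45 times higher in shPJA1 (1.74 to 3.52). BRCC3, a deubiquitinase of the BRCA1-A complex, was 2.28 times higher (1.42 to 3.79) and PC, pyruvate carboxylase, 2.53 times higher (1.37 to 4.99). PML, the scaffold of PML nuclear bodies, was 2.23 times higher (1.30 to 3.98). PJA1 was the lowest of these genes. POP7, a subunit of ribonuclease P, followed at 0.32 (0.16 to 0.64), and further lower genes included DEXI at 0.36 (0.19 to 0.66), TUBGCP5 of the gamma-tubulin complex at 0.38 (0.22 to 0.63) and NPM3 at 0.41 (0.23 to 0.71).

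Of 31 gene lists fixed in advance with at least 5 measured members, 5 had a median in shPJA1 against shCtrl outside the central 95% of 10000 random lists of matched expression. The number would be 1.55 if the members of a list varied independently. Genes of 1 list can vary together between cultures, which the random lists do not reproduce. All 5 were lower. Cytosolic ribosomal protein genes had a median log2 ratio of -0.15, with 42 of 55 below 0, among them RPS9 at 0.48 (0.36 to 0.64) and RPS2 at 0.50 (0.27 to 0.93). Oxidative phosphorylation genes had a median of -0.20, with 31 of 42 below 0, led by CYC1 at 0.62 (0.40 to 0.95) and NDUFB10 at 0.63 (0.39 to 1.00). DNA replication genes had a median of -0.22 at percentile 1.43. Of these 45 genes, 13 were lower by 1.5-fold, among them MCM2 at 0.42 (0.18 to 0.93), a subunit of the replicative helicase, and 3 were higher, among them the licensing factor CDC6 at 2.12 (1.07 to 4.50). Hepatocyte secreted proteins had a median of -0.11 at percentile 0.445, with FGB of fibrinogen at 0.45 (0.21 to 0.90). Genes of the unfolded protein and integrated stress response had a median of -0.13 at percentile 0.110, with the stress-induced secretory pathway gene MANF at 0.68 (0.48 to 0.96) and, against this direction, VLDLR at 1.82 (1.25 to 2.67). After removal of each library's trend with transcript GC content, a step added after seeing the data, the DNA replication, secreted protein and stress response lists no longer stood apart, at percentiles 5.57, 16.4 and 9.80.

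The TGF-beta/SMAD3 target genes did not stand apart in shPJA1 against shCtrl. The median log2 ratio of the 38 measured members was -0.0032 at percentile 38.6, with 2 higher and 2 lower by 1.5-fold. SPHK1, sphingosine kinase 1, was at 0.66 (0.54 to 0.80) and VASN, which binds TGF-beta, at 0.41 (0.17 to 0.92). BMP targets had a median of -0.0069 at percentile 50.1, with HEY1 at 0.49 (0.29 to 0.84), and TGF-beta family pathway components had -0.06 at percentile 5.98. Mesenchymal genes had a median of 0.01 and epithelial junction genes -0.04, at percentiles 54.3 and 19.6. N-cadherin, CDH2, was higher at 2.70 (1.20 to 6.85) from 28 against 8 reads, and tropomyosin TPM2 at 1.95 (1.09 to 3.64). The pro-apoptotic BAX was at 0.54 (0.32 to 0.90). Among immediate early genes, JUND was at 0.66 (0.52 to 0.83) and FOSB at 2.70 (1.05 to 8.16), with the list at percentile 25.9. The list of RING ligases and ubiquitin genes is mixed, with other ligases, deubiquitinases and proteasome subunits, and holds PJA1 itself. In it RNF128 was at 1.52 (1.20 to 1.93) and RNF6 at 1.49 (1.20 to 1.85), with a list median of 0.07 at percentile 92.6.

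The planned comparison for TGF-beta1 set the TGFb1 library against the library labelled water and titled shPJA/TGFb1. It gave 799 genes at least 2-fold higher and 532 at least 2-fold lower in TGFb1. Counting error alone gave 755.7 and 360.2, so the surplus lay mainly in the lower genes. PJA1 was 3.90 times higher in TGFb1 (1.7 to 11). SMAD7, SKIL and KLF10 had ratios of 1.06, 1.11 and 1.07, and ID1 0.88, each with an interval holding 1. JUNB and ID3 were lower in TGFb1, at 0.55 (0.40 to 0.77) and 0.52 (0.31 to 0.90). The genes leading by the size rule had 0 reads in the shallower library. DDT, a cytokine-like tautomerase, had 26 reads in TGFb1 against 0, at least 3.03-fold. IGFBP7 had 22 against 0 and the pro-apoptotic BBC3 had 18 against 0, at least 2.56-fold and 2.10-fold. The lowest were HIST1H2AG, with 1 read against 7 and a ratio of 0.050 (0.0011 to 0.39), and NOS2, inducible nitric oxide synthase, with 1 against 6 and a ratio of 0.058 (0.0013 to 0.48).

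In the gene lists the TGFb1 library and the library titled shPJA/TGFb1 differed in 11 of 31, of which 9 were lower in TGFb1. Replication-dependent histone genes had the most negative median among the lists with at least 10 members, -0.59, with 10 of 20 lower by 1.5-fold and none higher. HIST1H4C was at 0.38 (0.23 to 0.65) and HIST1H4E at 0.40 (0.31 to 0.52). Mitosis genes had a median of -0.38 with 16 of 46 lower by 1.5-fold, among them the spindle gene ASPM at 0.40 (0.21 to 0.75). Hepatocyte secreted proteins had -0.26, with 33 of 45 below 0, and collagens and extracellular matrix genes -0.20. The TGF-beta/SMAD3 targets had a median of -0.14 at percentile 0.260, lower in the TGFb1 library, with JUNB among them. Hepatocyte nuclear factors had -0.17, with 19 of 29 below 0 and, against this direction, HNF4G at 1.99 (1.16 to 3.62). Wnt targets had -0.14, stemness and oncofetal genes -0.13 and the 7 measured leukocyte markers -0.61, where CD79A was at 0.29 (0.11 to 0.74) from 10 against 12 reads. Heat shock and proteostasis genes had 0.17, with the mitochondrial chaperonin HSPD1 at 1.35 (1.19 to 1.54), and RING ligases and ubiquitin genes 0.13. With the GC trend removed the TGF-beta target, stemness, Wnt, nuclear factor and ubiquitin lists no longer stood apart. Without the filter the leukocyte median was -0.08 at percentile 18.8, and with quantile normalization the leukocyte and stemness lists were at percentiles 4.73 and 18.4, so these calls ended too. With unmatched random lists the heat shock list was at percentile 93.1. Outside the lists that stood apart, BIRC3, an NF-kappaB-induced inhibitor of apoptosis, was 2.13 times higher in TGFb1 (1.78 to 2.57).

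The shCtrl library against the library labelled water and titled shPJA/TGFb1 was planned as a background between controls. It gave 993 genes higher and 624 lower in shCtrl by 2-fold, 1617 in all, more than either other planned comparison. Counting error alone gave 811.9 and 593.7, and so part of the excess of higher genes. The total was 1.15 times that from counting error, against 1.19 times for TGFb1 against the same library. Where the counting interval had to exclude 1, these comparisons had 260 and 271 genes, so the order turned. PJA1 was 5.14 times higher in shCtrl (2.18 to 14.8). The TGF-beta/SMAD3 targets were lower in shCtrl, with a median of -0.24 at percentile 0. GADD45B was at 0.42 (0.22 to 0.79) and CTGF, a matricellular growth factor, at 0.50 (0.39 to 0.64). BMP targets had a median of -0.33, with ID1 at 0.53 (0.34 to 0.81), and glycolysis and hypoxia genes -0.14, with PFKP at 0.48 (0.27 to 0.82). With unmatched random lists the glycolysis and hypoxia list was at percentile 3.45, inside the random range. The ribosomal protein genes had 0.05 at percentile 98.0, and the same median at percentile 96.5 with the GC trend removed, just inside the random range. FOSB, an immediate early gene, was at 0.23 (0.074 to 0.59) and the mRNA decay factor ZFP36 at 0.42 (0.28 to 0.62).

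Genes that differed between shPJA1 and shCtrl showed little relation to those that differed in the planned TGFb1 comparison. These pairs share no library. If the title of the library labelled water is right, both libraries of the second pair hold TGFb1 and differ in the PJA1 hairpin. The relation then does not show how the responses to the hairpin and to TGFb1 compare. Across the 13387 genes Pearson's r was 0.022 and Spearman's rho 0.068, and genes are not independent replicates. At least 2-fold higher in both were 96 genes, against 32.1 for independent lists, and 68 were lower in both, against 22.4. Genes that went opposite ways were also more than independent lists give, 161 against 55.0, and both lists were dominated by genes of few reads. MCTP1, which encodes a calcium-binding membrane protein, led the genes higher in both, with 14 reads against 1 and 13 reads against 0. Among 10067 genes of a mean of at least 10, r was 0.093, and 3 genes were higher and 4 lower in both.

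By its title the library with conflicting labels holds both the hairpin and TGFb1. Comparisons that follow the title were added after seeing the data, and give TGFb1 pairs that share no library, TGFb1 over shCtrl and the library titled shPJA/TGFb1 over shPJA1. Across the 8575 genes of a mean of at least 20 the pairs were not alike, with an r of -0.064, a rho of -0.10 and 44.8% of genes of the same sign. The GC trends run opposite ways in these pairs, which pulls r down. At 60% GC they were 0.065 in shCtrl and -0.087 in TGFb1, but -0.037 in shPJA1 and 0.085 in the library titled shPJA/TGFb1. At this mean r was not recomputed without these trends. Beyond 2-fold 4 genes were higher in both, 1 lower in both and 2 opposite, against 0.099, 0.516 and 0.469 for independent lists. The genes named next were picked for going the same way in both. LSAMP, a neural cell adhesion gene of the IgLON family, was higher in both, at 6.95 (3.78 to 14.2) and 2.77 (1.74 to 4.47). SMAD7 was higher in both, at 2.02 and 2.28 (1.67 to 3.12). The stress gene GADD45B was at 2.09 (1.22 to 3.78) and 2.5 (1.38 to 4.61), the kinase gene SGK1 at 1.82 (1.22 to 2.80) and 2.43 (1.57 to 3.80), and the matricellular gene CYR61 at 1.79 (1.36 to 2.39) and 1.92 (1.41 to 2.62). The transporter ABCA5 was at 2.37 (1.5 to 3.9) and 2.10 (1.26 to 3.51). IER3, a stress-induced immediate early gene, was lower in both, at 0.33 (0.30 to 0.36) and 0.73 (0.65 to 0.83). RASD1, a Ras-related GTPase gene, was lower at 0.41 (0.32 to 0.52) and 0.69 (0.53 to 0.89), as was the stress-response factor DDIT3 at 0.60 (0.39 to 0.93) and 0.42 (0.20 to 0.79).

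**Figure D2:**
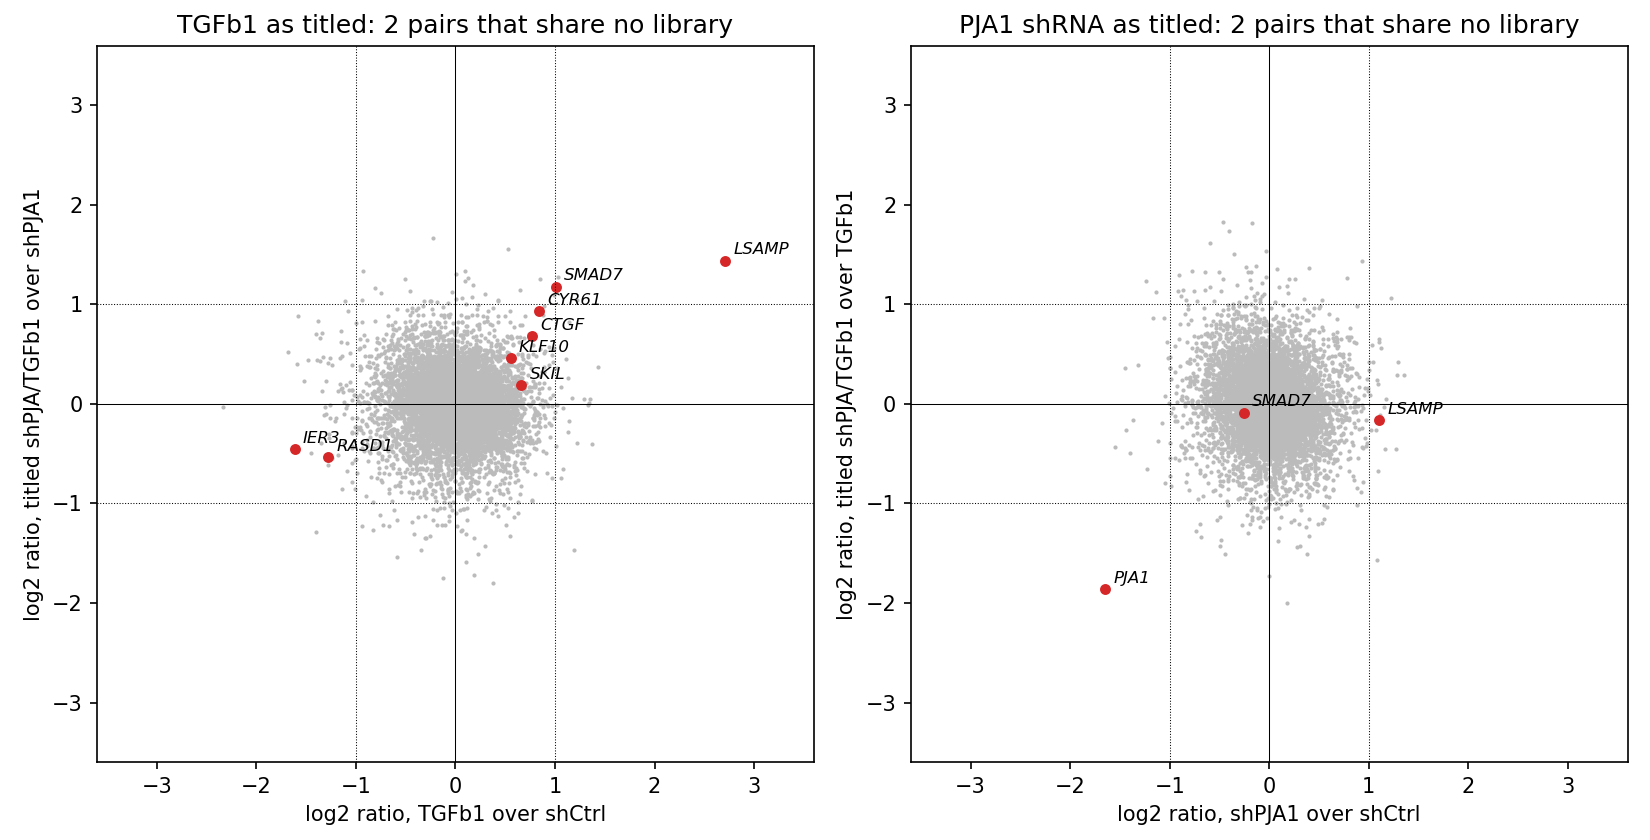
Log2 ratio of each of 8575 genes (mean normalized count at least 20, pseudocount 1) in 2 pairs of libraries that share none, for TGFb1 as titled (left) and for the PJA1 hairpin as titled (right), with 2-fold changes as dotted lines. LSAMP and SMAD7 lie above 0 on both axes and IER3 and RASD1 below on the left, and PJA1 stands alone at the lower left on the right.

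An edgeR quasi-likelihood fit to the recovered reads, with the hairpin and TGFb1 as additive terms by title, called 4 of 10210 genes for TGFb1 at an adjusted p under 0.05. LSAMP rose, with a log2 change of 2.03 ± 0.30 (SE, adjusted p = 8.587e-08 by edgeR), and SMAD7 rose by 1.09 ± 0.22 (adjusted p = 0.001411 by edgeR). IER3 fell, with -1.06 ± 0.17 (adjusted p = 9.049e-07 by edgeR), and RASD1 fell, with -0.94 ± 0.20 (adjusted p = 0.01152 by edgeR). For the hairpin the fit called 1 gene, PJA1, which fell, with -1.80 ± 0.37 (adjusted p = 0.01553 by edgeR), and 0 genes rose. An unadjusted p under 0.05 by edgeR was reached by 383 of the 10210 genes for TGFb1 and by 235 for the hairpin. Each is a smaller share than the 0.05 that no effect would give. The fit has 1 residual degree of freedom, which is the departure from additivity. It therefore compares these 4 libraries and not replicated conditions. The sorting by title was added after PJA1 and SMAD7 of the library with conflicting labels had been seen to go with its title. The calls of PJA1 and SMAD7 therefore partly restate those values. The SE printed for this fit was computed back from the log2 change and the test statistic, so it restates the p. Both rest on a spread shared across genes, and not on how far a gene's own pairs differ. For IER3 the pairs differed widely. Its normalized count was 1198 in shCtrl and 390 in TGFb1, but 825 in shPJA1 and 603 in the library titled shPJA/TGFb1. RASD1 and LSAMP differed between the pairs as well. In the same order of libraries RASD1 had 183.5, 75.2, 194.5 and 133.7, and LSAMP had 12.9, 89.4, 28.8 and 79.9. The pairs of SMAD7 were closer, at 83.0, 168.0, 69.3 and 158.1. PJA1 was no longer called with the GC trend as an offset or without the TGFb1 term, at nearly the same change (-1.78 and -1.70, adjusted p = 0.1248 and 0.3367 by edgeR). DESeq2 on the same model called 0 genes for either term, with 23 and 4 genes at an unadjusted p under 0.05, also below that share. For TGFb1 the unadjusted p of IER3 was 0.06472 by DESeq2. Those of LSAMP, SMAD7 and RASD1 were 0.0001022, 0.001514 and 0.005813 by DESeq2.

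TGF-beta/SMAD3 targets were higher in the library titled shPJA/TGFb1 than in shPJA1, with a median log2 ratio of 0.23, above all 10000 matched lists, and 31 of 38 members above 0. In TGFb1 over shCtrl the median was 0.12 at percentile 92.7, inside the random range, with 22 of 38 above 0. With the GC trend removed both medians were 0.18, at percentiles 99.9 and 100. BMP targets had a median of 0.44 against shPJA1 and -0.07 in TGFb1 over shCtrl, at percentiles 99.8 and 42.7. NRF2 targets and metallothioneins were higher in both pairs, at 0.22 and 0.10, with the zinc exporter SLC30A1 at 1.72 (1.49 to 1.99) in TGFb1 over shCtrl and heme oxygenase HMOX1 at 1.96 (1.09 to 3.51) in the other pair. With the GC trend removed the second median was 0.06, at percentile 83.1, and with quantile normalization it was at 97.1, inside the random range.

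Further lists stood apart in only 1 of the TGFb1 pairs, and the difference between pairs was not tested. In TGFb1 over shCtrl the histone genes had a median of -0.51, with HIST1H4E at 0.31 (0.25 to 0.38), and the secreted proteins -0.24, with coagulation factor F7 at 0.37 (0.21 to 0.67). Stemness and oncofetal genes had -0.16, with SOX12 at 0.57 (0.39 to 0.85). Heat shock genes had 0.18, with HSP90AA1 at 1.30 (1.21 to 1.39), and the ubiquitin genes 0.15, with the E2 enzyme UBE2D1 at 1.57 (1.07 to 2.37). With the GC trend removed the stemness and ubiquitin lists moved inside the random range, to percentiles 8.23 and 91.4. The heat shock list, at percentile 97.6, moved inside it without the filter (97.4), with quantile normalization (96.7) and with unmatched lists (95.9). The other TGFb1 pair, the library titled shPJA/TGFb1 over shPJA1, gave histone genes 0.17 and secreted proteins 0.06. It gave stemness genes 0.02, heat shock genes -0.09 and ubiquitin genes 0.0006. All of these lay inside the random range. In the library titled shPJA/TGFb1 over shPJA1 the glycolysis and hypoxia genes had 0.13 and the ribosomal proteins 0.10, with RPS9 at 1.74 (1.26 to 2.41), and the former moved to percentile 91.4 with the GC trend removed. With unmatched lists the glycolysis and ribosomal lists of that pair moved inside the random range too, to percentiles 97.2 and 96.9. Their medians in TGFb1 over shCtrl were 0.11 and -0.01, inside the random range. DNA replication and oxidative phosphorylation genes stood apart in both pairs, in opposite directions, at -0.31 and 0.20 for the former and -0.15 and 0.15 for the latter. The -0.15 for oxidative phosphorylation was at percentile 3.09 with unmatched lists, inside the random range.

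**Figure D3:**
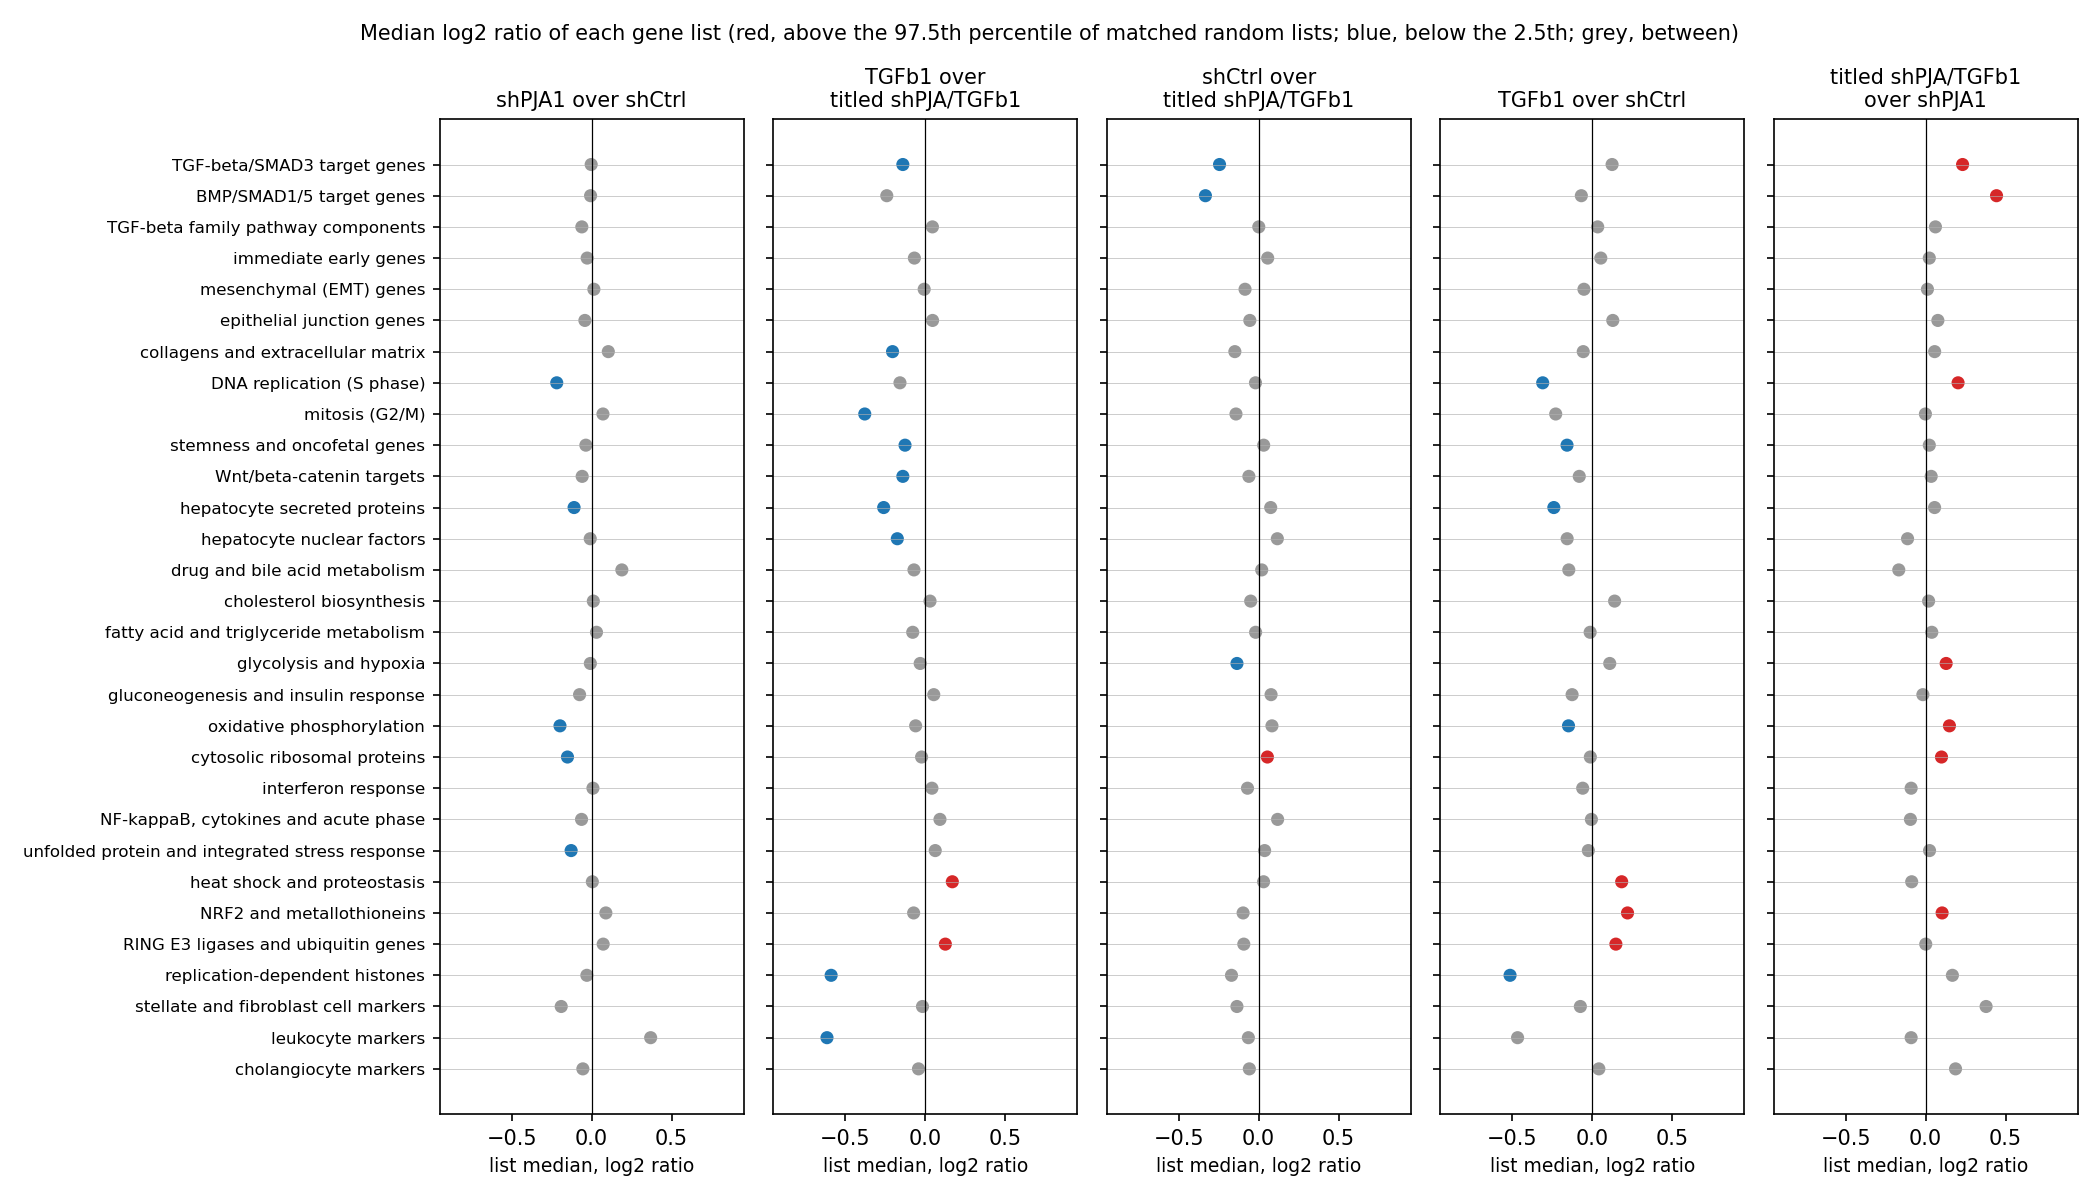
Median log2 ratio of gene lists in 5 pairs of libraries (pseudocount 1), in red above and in blue below the central 95% of 10000 random lists matched on expression. The TGF-beta/SMAD3 target list lies at -0.24 in shCtrl over the library titled shPJA/TGFb1 and at 0.23 in that library over shPJA1, and the histone list at -0.59 and -0.51 in the comparisons of TGFb1. Those comparisons share the TGFb1 library, and the histone list lies at 0.17 in the library titled shPJA/TGFb1 over shPJA1.

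For the hairpin the pairs by title are shPJA1 over shCtrl and the library titled shPJA/TGFb1 over TGFb1. Across 8575 genes of a mean of at least 20 their log2 ratios had an r of -0.13 across genes, and PJA1 was the only gene beyond 2-fold lower in both. The GC trends of the libraries run opposite ways in these pairs too, which pulls r down. The only gene beyond 2-fold higher in both was ZC3H4, which restrains non-coding transcription, at 2.42 (1.30 to 4.78) and 2.15 (1.21 to 3.76). It had an additive log2 change of 1.18 ± 0.35 that missed the threshold (adjusted p = 0.9999 by edgeR). None of the 5 lists that were lower in shPJA1 stood apart as lower in the second pair. There, taken as TGFb1 over the library titled shPJA/TGFb1, ribosomal proteins had a median of -0.022, oxidative phosphorylation -0.06, DNA replication -0.16 and secreted proteins -0.26, which is the opposite direction for the hairpin. The stress response list had 0.06 at percentile 73.2. BIRC3 had an additive log2 change of -0.57 ± 0.18 and the secretory pathway gene TMED9 0.69 ± 0.21, which also missed it. Both were called, with PJA1 and SPOCK2, when the split of TGFb1 and shPJA1 from the other libraries replaced the TGFb1 term.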

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

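The test of GC content and that of transcript length were set before their results were seen, and the test of counting error after. The lists were compared between pairs after seeing the data, and none of these differences was tested.

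DNA replication genes had a median log2 ratio of -0.31 in TGFb1 over shCtrl and of 0.20 in the library titled shPJA/TGFb1 over shPJA1, so a contrast titled alike went opposite ways. Oxidative phosphorylation genes did so too, at -0.15 and 0.15. For the hairpin, hepatocyte secreted proteins had -0.11 in shPJA1 over shCtrl and 0.26 in the library titled shPJA/TGFb1 over TGFb1. With the GC trend of each library removed, the DNA replication medians were -0.26 and 0.17 and the oxidative phosphorylation medians -0.11 and 0.12, all still outside the central 95% of matched random lists. With unmatched random lists and no GC removal, oxidative phosphorylation in TGFb1 over shCtrl was at percentile 3.09, inside that range. The secreted protein medians became, with the GC trend removed, -0.04, inside that range, and 0.18, outside it.

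These lists follow a wider pattern, in which the TGFb1 and shPJA1 libraries differed together from shCtrl and from the library titled shPJA/TGFb1. The SD of this split's log2 difference over 6166 genes of a mean of at least 50 was 0.209, against 0.136 in Poisson simulations. Every split of these separate cultures exceeded its simulation, so this comparison says nothing particular to the pattern. GC content of the transcripts is a candidate explanation for part of it, with a Spearman rho across genes of -0.46 between the difference and GC content. Removing the GC trend lowered the SD to 0.179. The splits by TGFb1 and by the hairpin as titled had an SD of 0.188 and 0.174, and 0.185 and 0.172 with the GC trend removed, so what remains of this split lies between them and does not mark it as distinct. Transcript length had a rho of 0.16, between the bounds set for it, and 0.033 once the GC trend was removed, which leaves its share open. By title this split is also the interaction of the hairpin with TGFb1, which 1 library per condition cannot separate from a difference in library preparation.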

How the results depend on the processing

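The mean of at least 20, the counting interval, the GC removal and every count fit were chosen after seeing the data; the other settings were fixed before. No analysis paired across replicates was possible because each condition has 1 library, which also rules out leaving a library out of a group. By title the 4 libraries form 2 TGFb1 pairs, without and with the PJA1 hairpin, and the additive fit used them so. Median-ratio rescaling left the 2-fold counts at 1101, 1326 and 1617, because the deposited values already carry those factors.

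The 2-fold counts depend on how low genes are treated. For shPJA1 against shCtrl, TGFb1 against the library labelled water, and shCtrl against that library, they were 134, 234 and 349 with a pseudocount of 5; 375, 517 and 609 at a mean of at least 5; and 1819, 2100 and 2775 without a filter. They were 2734, 3159 and 3255 by a 1.5-fold rule, 44, 112 and 141 at a mean of at least 20, and 173, 271 and 260 where the counting interval had to exclude 1. The split moved too. Of the 1819, 687 were higher in shPJA1, and of the 112, 56 were higher in TGFb1. With quantile normalization 675 were higher and 691 lower in TGFb1, and 760 and 764 in shCtrl, so the excess of higher genes in these comparisons was lost. Pseudocount 0.1, upper-quartile and quantile scaling, rescaling without the 100 most abundant genes and the GC removal kept the counts within 1.5 times. Pearson's r of the planned comparisons turned from 0.022 to -0.0048 with a pseudocount of 0.1, -0.026 with crossed controls and -0.0027 with the GC trend removed, and was 0.093 at a mean of at least 10. Spearman's rho stayed above 0, at 0.065, 0.028 and 0.010 in the first 3 of these settings. No value was far from 0, and the cause was not tested.

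The number of lists standing apart in TGFb1 against the library labelled water went from 11 to 6 with unmatched random lists and to 7 with the GC trend removed. That against shPJA1 went from 7 to 4 with unmatched lists. None of the 35 list results that stood apart changed direction in any setting. Together with 13 named gene ratios, 13 of 48 results lost their side of the threshold with the GC trend removed, 16 of 35 lists with unmatched lists, 6 of 48 with quantile normalization and at most 3 in the other settings. The log2 ratio of PJA1 in shPJA1 over shCtrl, -1.65, stayed beyond 2-fold in each.

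In the additive fit the 4 TGFb1 calls became 11 with the GC trend as an offset, 11 without the hairpin term and 32 with the split of TGFb1 and shPJA1 from the other libraries in place of the hairpin, each holding the first 4, and 0 by DESeq2. The PJA1 call became 0 with the GC offset, where its log2 change was -1.78 ± 0.35 against -1.80 ± 0.37 (adjusted p = 0.1248 by edgeR), 0 without the TGFb1 term (-1.70 ± 0.35, adjusted p = 0.3367 by edgeR), 0 by DESeq2 (-1.82) and 4 with that split in place of TGFb1. Over these fits its change ranged from -1.82 to -1.68, and why the calls ended was not tested. Depth limits low genes most, since 3 reads are a normalized count of 4.89 in the shallowest library.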

Other observations

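The tests of the library's labels were chosen only after its values were seen. Those of GC content and of the target genes were set before their results were.

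BAX, which promotes apoptosis, was lower in shPJA1 and in TGFb1 than in the other libraries. Its ratio to shCtrl was 0.54 (0.32 to 0.90) in shPJA1 and 0.46 (0.29 to 0.74) in TGFb1, and 0.44 (0.27 to 0.74) in TGFb1 against the library titled shPJA/TGFb1. CTGF and CYR61, matricellular genes, and SMAD7 were higher in both libraries titled with TGFb1. The mesenchymal list, with 18 measured genes, stood apart in neither TGFb1 pair, at percentiles 31.2 and 60.2.

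Markers of other cell types were few. Of 16 leukocyte markers 7 were measured, of 14 stellate and fibroblast markers 5, of 12 cholangiocyte markers 8 and of 12 endothelial markers 4. The stellate and cholangiocyte lists stood apart in no pair, and the leukocyte list in TGFb1 against the library titled shPJA/TGFb1 alone, a call that ended without the filter and with quantile normalization.

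The library with conflicting labels was weighed against each label. A water-treated culture without the hairpin would hold PJA1 at the level of shCtrl, but its ratio was 0.195 with a counting interval of 0.068 to 0.46. The title needs PJA1 below TGFb1 and SMAD7 above shPJA1, and these ratios were 0.256 (0.091 to 0.59) and 2.28 (1.67 to 3.12). The values are consistent with the title. Between-library spread was not measured, and a different mislabelled culture with both features stays open.

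IER3 and RASD1, lower in both libraries titled with TGFb1, are GC-rich, at 58.5% and 61.6% against a median of 47.1% for genes of a mean of at least 20. GC content of the transcripts could lower such genes together. With the GC offset their log2 changes in the edgeR fit were -1.05 and -0.92, against -1.06 and -0.94 without it. At 60% GC the library trends ran only from -0.087 in TGFb1 to 0.085 in the library titled shPJA/TGFb1. An offset of that size could not have ended these calls, so that both remained called is no separate evidence. The trend across genes was too small to be the whole cause, and other effects of GC content were not tested. A repression by TGF-beta1 within the hour is a hypothesis that these libraries cannot test apart from chance differences between cultures.

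A hypothesis of interest for this design is that PJA1 knockdown may raise the response of TGF-beta/SMAD3 target genes to TGFb1. The list's median response was 0.10 larger on the log2 scale in the pair with the hairpin than in the pair without it, at percentile 94.2 of matched random lists. With the GC trend removed the median difference was -0.02, at percentile 38.6, with 18 of 38 members higher, so these data did not show a larger response. The libraries would need replicates to bound one.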
